A study of Bos taurus with 12 samples.

How the data were processed

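Mammary tissue biopsies were taken from 12 cows, and total RNA from each cow's samples under once-daily milking and under milking 2 times a day was amplified, labelled with Cy3 or Cy5 and hybridised to 1 array per cow. Each array is therefore its own within-cow comparison of 2 biopsies, and the 12 arrays are separate animals. Milking frequency goes with biopsy time point in this design, and the order of the biopsies is not given in the sources used here. Per the labels, 6 arrays carried the once-daily RNA in Cy5 (unswapped) and 6 carried it in Cy3 (swapped).

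The values analysed were the deposited log2 ratios of the 2 channels, 1 per probe and array. Per the labels' description, experimental probes were normalised by the authors and control spots were not. The normalisation method, the scanner software and the direction of the log2 ratio are not given in the sources used here. The log base was read from the table itself, because its lowest value, -6.6439, equals the base-2 logarithm of a ratio of 0.01. The deposited table held 21844 rows with 0 missing values, and column medians over the tested probes lay between -0.00095 and 0.0014. Spot brightness and background were not analysed here, so no filter on dim spots could be applied, and the number of arrays limits the precision. The 4 control spots were left out of every test, which left 21840 probes.

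The probe identifiers have the form of a number, a contig and a position, and the table does not pair them with genes. None of them (0) matched a symbol, synonym, locus tag or accession among the 37063 genes of the bovine reference table (assembly ARS-UCD2.0). The 30 gene lists prepared before the data were examined, covering milk synthesis, involution, stress, defence and markers of other cell types, could therefore not be tested, and no gene, pathway or genomic position is named. Without gene names, the rule fixed beforehand allows at most 2 probes in each direction. Identifiers are printed for these probes over all cows only, and further probes of the other comparisons are described by their rank. Over all cows these were the probes with the largest changes among those with an adjusted p under 0.05 and the same sign on 10 or more arrays. Within a yield-loss group they were the largest changes among called probes. For the difference between groups, where no probe passed, they were the 2 with the smallest p in each direction, and they are said not to have passed. Averaging probes of a gene was likewise not possible, so each probe was tested on its own.

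Groups came from the sample titles, which give 5 low-loss and 7 high-loss cows, whereas the series' design text states 6 in each group with 3 per dye orientation. The titles give 2 unswapped and 3 swapped low-loss arrays, and 4 unswapped and 3 swapped high-loss arrays. For high-loss cow 5 the source names of both channels name the milking of 2 times a day, while the characteristics give once daily for the Cy3 channel, and the characteristics were used. Cows are numbered by the replicate number of their title.

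The sign of the ratios needed a decision. A rule fixed before the data were examined would have turned the swapped arrays if their mean correlation with the unswapped arrays lay under -0.1, and left them if it lay above 0. The mean over 36 pairs was -0.088 over the tested probes and -0.124 with the control spots included, so the outcome depends on whether the control spots count as probes. Read word for word, over all probes, the rule would have turned the swapped arrays. Over the tested probes neither of its conditions was met. The values were nevertheless used as deposited, a choice made after these correlations and the control spots had been seen and before any count of calls was known. The reason was that a control spot with a ratio of about 100 to 1 averaged 6.72 ± 0.20 (SD, n = 6) on unswapped arrays and at most -6.51 on swapped arrays, where 3 of 6 values lay at the floor of the table, so that no SD is given. A control target that carries a single dye would read so if the authors had already turned the swapped arrays. Another control spot changed sign in the same way (6.61 unswapped, at most -6.46 swapped). The remaining control spots had small ratios and kept the sign of their mean, at 0.10 and 0.43 on unswapped and 0.26 and 0.10 on swapped arrays. Whether the target of the first spot carried a single dye is not stated. Per the labels the control spots were not normalised, dye swaps included, so they may not have been turned in the same way as the probes. The direction is therefore unsettled. The numbers of called probes in the main model, the overlaps of calls and the shares of equal sign are also given with the swapped arrays turned, and so are the ranges of these counts with single arrays left out. Under the values as deposited, a positive ratio is likely to mean more RNA with once-daily milking, since the unswapped arrays hold that RNA in channel 1. If the authors divided the other way, every sign reverses and no count changes.

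The main test was limma 3.58.1 in R 4.3.3. A single linear model over the 12 arrays had a coefficient for low-loss cows, a coefficient for high-loss cows and a dye-orientation term, with empirical Bayes moderation on 9 residual degrees of freedom. The contrasts were the equally weighted mean of both groups, each group alone, and high-loss minus low-loss. The p-values of limma were two-sided and were adjusted by Benjamini-Hochberg over the probes tested, with a threshold of 0.05. On simulated arrays with the real residual spread and dye terms, the all-cow contrast recovered 91.0% of 200 probes changed by 0.5 on the log2 scale and 99.5% of 200 changed by 1. The contrast between groups recovered 48.0% and 92.5%, respectively. Smaller changes were not simulated, although the median size of the changes called over all cows was 0.24. These simulations had independent errors, whereas probes on the real arrays vary together.

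Alternatives were median centring, scaling of the arrays to a common median absolute deviation, no dye term, swapped arrays turned, array weights, robust moderation, an unmoderated test, 1 mean over all arrays, a replicate block, each unswapped high-loss array moved to the low-loss group in turn, and each array left out in turn. Fits within each dye orientation, the leaving out of arrays with the swapped arrays turned, and the comparison of array correlations within and between groups, were added after seeing the data. Figures were drawn with matplotlib 3.10.9.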

Results

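The response of the bovine mammary gland to milking 1 time instead of 2 times a day was measured in 12 lactating cows on two-colour expression arrays. The cows had earlier shown a small (low-loss, 5 cows by the sample titles) or a large (high-loss, 7 cows) drop in milk yield under once-daily milking. The comparisons ask which transcripts differ between the 2 milking frequencies, and whether that change differs between the 2 kinds of cow. The SD of the log2 ratios over the 21840 probes ranged from 0.22 in low-loss cow 5 to 0.50 in high-loss cow 4. The share of probes beyond 2-fold ranged from 0.27% (58 probes) to 4.17% (910 probes) in the same cows. No probe could be named as a gene from the table, so results are given by probe and by group of cows.

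Profiles of the 6 unswapped arrays resembled one another, with Pearson correlations over probes between 0.36 and 0.77 (mean 0.57, 15 pairs). The 6 swapped arrays correlated less closely, between -0.14 and 0.57 (mean 0.33, 15 pairs). Across orientations the correlations ran from -0.53 to 0.47 (mean -0.088, 36 pairs). Low-loss cow 3 and high-loss cow 5 correlated below 0 with all 6 unswapped arrays, and high-loss cow 7 above 0 with all 6. Probes are not independent replicates, and these correlations describe the arrays only. The fitted dye term passed the test at 8082 probes, 3 of them beyond 2-fold, so in the values as deposited more probes went with the dye orientation than with milking frequency. No cow was run in both orientations, and the unswapped arrays all come before the swapped ones in the numbering of the titles. The dye term therefore also holds any difference between these sets of cows or with array order. With the swapped arrays turned, the dye term passed at 2413 probes.

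**Figure D1:**
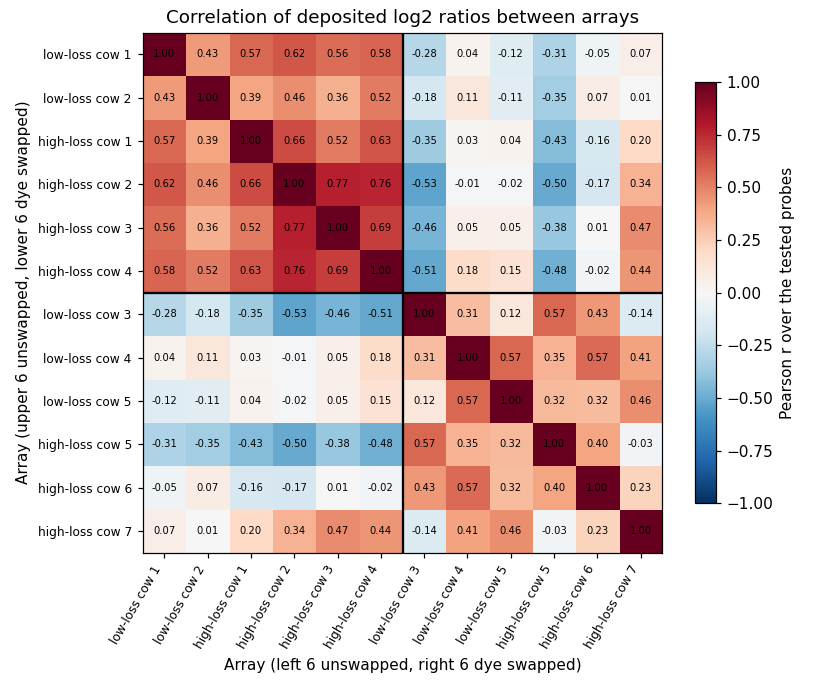
Pearson correlation of deposited log2 ratios over the 21840 tested probes for each pair of the 12 arrays, with black lines between the 6 unswapped and the 6 swapped arrays. Correlations among unswapped arrays lie between 0.36 and 0.77, and those across orientations between -0.53 and 0.47.

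Over all cows, 2687 of the 21840 probes (12.3%) differed between once-daily milking and milking 2 times a day, 1526 with a positive and 1161 with a negative ratio (limma, adjusted p under 0.05). With the swapped arrays turned, the other reading of an unsettled sign, 7759 probes differed. A positive ratio stands for more RNA under once-daily milking only if the authors divided in that direction, which is not stated. Most changes were small. The median size among called probes was 0.24 on the log2 scale (0.22 turned), and 16 called probes, 14 positive and 2 negative, passed 2-fold. The probe with the largest rise in the ratio, 30865.C1_454, had a log2 change of 1.92 ± 0.14 (SE), a 3.79-fold difference (adjusted p = 1.85e-05, limma), and was positive in 12 of 12 cows, from 0.99 to 2.88. Probe 448.C1_512 followed at 1.58 ± 0.17 (SE; adjusted p = 0.00024, limma), also positive in 12 of 12 cows. On the negative side, probe 30661.C1_241 changed by -1.26 ± 0.17 (SE; adjusted p = 0.00097, limma) and probe 4838.C1_588 by -1.10 ± 0.083 (SE; adjusted p = 2.00e-05, limma), both negative in 12 of 12 cows. In all, 343 probes had the same sign in all 12 cows, 200 positive and 143 negative, and with the swapped arrays turned 1344 did, 508 positive and 836 negative. If signs were independent between cows, 10.7 would be expected under either reading. Signs were not independent, because arrays of 1 orientation correlated with one another (mean 0.57 unswapped, 0.33 swapped). The excess over 10.7 is therefore no measure of a response to milking.

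These 4 probes kept their sign on both dye orientations in the deposited values, which their choice by the same sign on 10 or more arrays nearly fixed. Probe 30865.C1_454 averaged 2.03 ± 0.50 (SD, n = 6) on unswapped and 1.84 ± 0.60 (SD, n = 6) on swapped arrays. Probe 4838.C1_588 averaged -0.98 ± 0.33 (SD, n = 6) and -1.22 ± 0.28 (SD, n = 6). With the swapped arrays turned, the 7759 called probes were 3944 positive and 3815 negative, with 3 beyond 2-fold. Only 1041 probes were called under both readings. None of the 4 named probes passed under that second reading, where their changes were 0.088, 0.39, 0.42 and 0.14, in the order named. This follows largely from their choice, since similar values on both orientations cancel when the swapped arrays are turned. The number of calls also moved with single arrays. It was 4818 without high-loss cow 5, whose channel labels disagree. It was 873 without low-loss cow 4, 1356 without low-loss cow 2, 1383 without low-loss cow 5, and 1760, 1742, 1629 and 1759 without high-loss cows 2, 3, 4 and 7. Other cows stood out with the swapped arrays turned, where it ran from 5791 without low-loss cow 3 to 9825 without high-loss cow 7, with 6315 without high-loss cow 5. In the values as deposited, the count was 776 without the dye term, 8255 with array weights (4132 positive and 4123 negative), 1399 in the unmoderated test and 4133 with high-loss cow 1 counted as low-loss.

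**Figure D2:**
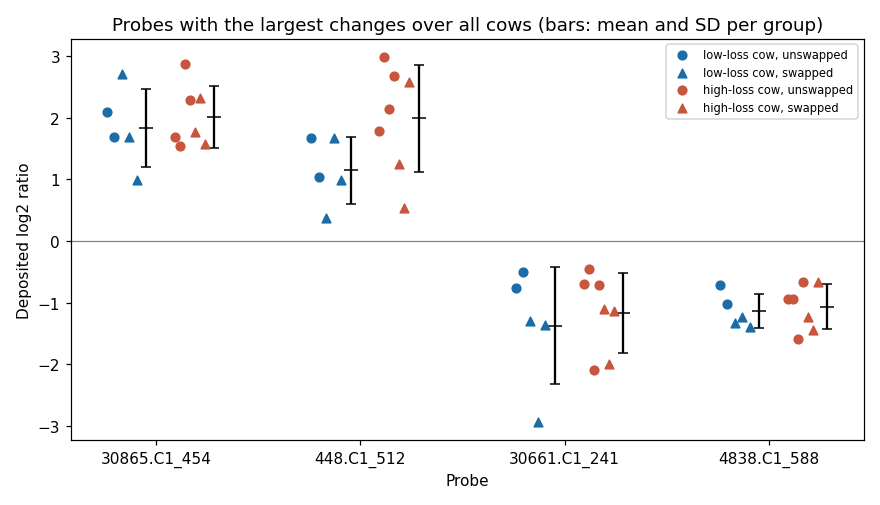
Deposited log2 ratio (vertical axis, no unit) of the 4 probes with the largest changes over all cows, 1 point per cow, with the mean and SD of each yield-loss group beside the points. Both probes on the left are positive in 12 of 12 cows and both on the right negative in 12 of 12, on unswapped arrays (circles) and swapped arrays (triangles). The probes were chosen partly for the same sign on 10 or more arrays.

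In low-loss cows taken alone, 32 probes (713 with the swapped arrays turned) differed with milking frequency, 21 positive and 11 negative (301 and 412 turned), with a median size of 0.61 on the log2 scale (0.36 turned). Probe 30865.C1_454 changed by 1.85 ± 0.22 (SE; adjusted p = 0.0043, limma), and the next largest positive change was 1.57 ± 0.21 (SE; adjusted p = 0.014, limma). Probe 4838.C1_588 changed by -1.12 ± 0.13 (SE; adjusted p = 0.0038, limma) and the next largest negative change was -0.86 ± 0.13 (SE; adjusted p = 0.025, limma). In high-loss cows taken alone, 2025 probes (5589 with the swapped arrays turned) differed, 1223 positive and 802 negative (2789 and 2800 turned), with a median size of 0.33 (0.28 turned). Of the called probes 52 were beyond 2-fold, and 5 with the swapped arrays turned. The median sizes of calls do not compare the groups, since a change had to be larger to pass in low-loss cows. The median SE was 0.084 in low-loss and 0.0705 in high-loss cows. Over all probes, with equal weight for each dye orientation, the SD of the changes was 0.15 in low-loss and 0.19 in high-loss cows. The probe with the largest positive change in high-loss cows had 2.02 ± 0.35 (SE; adjusted p = 0.0056, limma) and was positive in 10 of 12 cows. Its ratio was -0.60 in high-loss cow 6, 0.74 in high-loss cow 5 and 2.50 to 3.38 in the other high-loss cows. It changed by 0.72 in low-loss cows, where it did not pass (adjusted p = 0.50, limma). Its difference between the groups, 1.29, did not pass either (adjusted p = 0.74, limma). Over all cows it averaged 2.28 ± 0.97 (SD, n = 6) on unswapped and 0.68 ± 1.48 (SD, n = 6) on swapped arrays. Probe 30865.C1_454 followed at 1.99 ± 0.18 (SE; adjusted p = 0.00024, limma). The largest negative changes in high-loss cows were those of probe 30661.C1_241, at -1.22 ± 0.22 (SE; adjusted p = 0.0076, limma), and of another probe, at -1.10 ± 0.14 (SE; adjusted p = 0.0011, limma). These ranks hold for the values as deposited only. None of these changes passed with the swapped arrays turned, and in the order given they were 0.063, -0.023, 0.23 and 0.043 in low-loss cows and 0.93, 0.11, 0.21 and 0.26 in high-loss cows.

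Of the 32 probes called in low-loss cows, 29 were also called in high-loss cows, all 29 with the same sign, against 2.97 expected for independent lists of these sizes. Both lists come from 1 model with a common dye term and spread, so the lists are not fully independent. Of the 2025 called in high-loss cows, 1912 had the same sign in low-loss cows. With the swapped arrays turned, 666 of 713 low-loss calls were also called in high-loss cows, all 666 with the same sign, against 182.5 expected for independent lists, and 5516 of 5589 high-loss calls had the same sign in low-loss cows. When each group's change was averaged from its own arrays with equal weight for each dye orientation, the changes correlated across probes at r = 0.53 (Spearman's rho 0.49), and 68.0% of probes had the same sign in both groups. Probes are not independent replicates, so no p is attached. Leaving out single cows moved this r between 0.41 (without low-loss cow 5) and 0.67 (without low-loss cow 3). With the swapped arrays turned r was 0.79, and 81.5% of probes had the same sign.

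The 2 counts depended on the scaling and weighting of the arrays, on the model and on the group labels. After scaling to a common spread, 480 probes were called in low-loss and 643 in high-loss cows. Array weights gave 923 and 7040, the model without the dye term 7 and 601, and the unmoderated test 6 and 746. Counting 1 of the 4 unswapped high-loss cows as low-loss, as the design text would require, gave 138 to 428 in low-loss and 429 to 3685 in high-loss cows. Without single cows the low-loss count ran from 5 (without low-loss cow 4) to 56 (without high-loss cow 7), with 7, 9 and 10 without low-loss cows 1, 2 and 3 and 12 without high-loss cow 2 or 6. The high-loss count ran from 506 (without high-loss cow 7) to 5540 (without high-loss cow 5), with 853, 614, 660 and 845 without high-loss cows 2, 3, 4 and 6 and 1302 without low-loss cow 1. The ranges with the swapped arrays turned were 73 (without low-loss cow 2) to 1180 (without high-loss cow 7) in low-loss cows and 2376 (without high-loss cow 5) to 8611 (without high-loss cow 7) in high-loss cows.

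**Figure D3:**
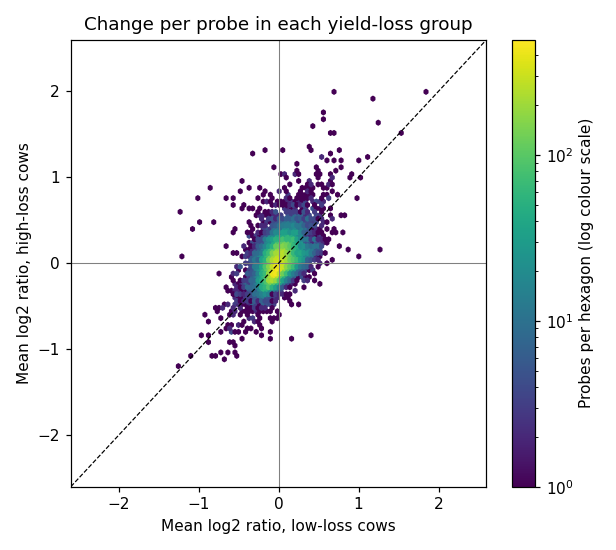
Mean log2 ratio of each of the 21840 probes in low-loss cows (horizontal axis) and high-loss cows (vertical axis), each the mean of that group's unswapped and swapped means, with the number of probes per hexagon as colour on a log scale and the line of equal change dashed. Changes in the 2 groups correlate at r = 0.53 in the values as deposited, and 68.0% of probes share a sign.

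The test of the difference itself found no probe whose change with milking frequency differed between high-loss and low-loss cows. The count was 0 of 21840 with limma at adjusted p under 0.05, against 1188 probes (5.44%) at an unadjusted p under 0.05. It was also 0 with the swapped arrays turned (295 probes at an unadjusted p under 0.05), 0 in the unmoderated test (1007 probes), 0 on unswapped arrays alone (1687 probes) and 0 on swapped arrays alone (315 probes), where neither the dye nor the reading of the sign enters. The 2 probes with the smallest p in each direction did not pass. The first positive one averaged 1.27 ± 0.53 (SD, n = 7) in high-loss and -0.37 ± 0.72 (SD, n = 5) in low-loss cows. Its difference was 1.59 ± 0.31 (SE; adjusted p = 0.74, limma), with an unadjusted 95% interval of 0.93 to 2.26. The second positive probe differed by 0.95 ± 0.21 (SE), and the 2 negative ones by -0.35 ± 0.085 (SE) and -0.53 ± 0.13 (SE), all with an adjusted p of 0.74 (limma). The 4 differences were -0.40, 0.29, 0.027 and 0.15 with the swapped arrays turned, and none passed. In the values as deposited, the 95% interval of the difference lay within 2-fold in both directions for 21488 probes (98.4%). Few called changes were themselves beyond 2-fold, so this share says little about smaller differences. The median half-width was 0.24 on the log2 scale, as large as the median size of the changes called over all cows (0.24). The share and the half-width were not computed with the swapped arrays turned.

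The arrays as a whole did not separate by yield-loss group either. Within a dye orientation, the mean correlation was 0.47 between cows of the same group and 0.43 between cows of different groups, a difference of 0.032 (one-sided exact permutation p = 0.34 over 300 relabellings within orientation). The difference turned negative, from -0.059 to -0.021, when any one of the 4 unswapped high-loss arrays was counted as low-loss, as the 6 and 6 cows of the design text would require, and also without high-loss cow 1, 2, 3 or 4 (-0.0019 to -0.033). These means pool both orientations, and unswapped pairs correlated more closely than swapped pairs. The difference thus also depends on how many pairs of each orientation enter each mean. Same-group pairs tended to correlate more closely than different-group pairs on unswapped arrays (0.43 to 0.77 against 0.36 to 0.62). On swapped arrays they did not (-0.031 to 0.57 against -0.14 to 0.57). The orientations were not tested separately.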

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

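The fits on 1 dye orientation only, the leaving out of arrays with swapped arrays turned and the comparison of array correlations were chosen after the results were seen. The difference between groups stayed at 0 calls under every alternative run, the replicate block with the dye term included (0 calls). Cows with the same number in both groups are different animals, and their residual profiles correlated from -0.40 to 0.52 over 5 pairs. For number 4 this correlation (0.52) exceeded the highest of that low-loss cow with another number (0.33), and for the other numbers it did not. So few pairs cannot show whether the numbers pair anything. Counts over all cows, in low-loss and in high-loss cows, in that order, were 776, 7 and 601 without the dye term, 7759, 713 and 5589 with swapped arrays turned, 8255, 923 and 7040 with array weights, 1399, 6 and 746 in the unmoderated test, 7779, 0 (3560 at an unadjusted p under 0.05) and 9419 on unswapped arrays only and 1153, 8 and 43 on swapped arrays only, where dye and milking frequency cannot be separated. Scaling gave 480 in low-loss and 643 in high-loss cows. Counting unswapped high-loss cow 1, 2, 3 or 4 as low-loss gave 219, 138, 158 and 428 in low-loss and 3685, 1260, 429 and 520 in high-loss cows, and for cow 1 gave 4133 over all cows. Leaving out 1 array gave 873 to 4818 over all cows, 5 to 56 in low-loss and 506 to 5540 in high-loss cows, and with swapped arrays turned 5791 to 9825, 73 to 1180 and 2376 to 8611. Median centring, robust moderation and, over all cows, scaling or 1 mean over the 12 arrays stayed within 1.5 times of the main counts. The positive share in low-loss cows was 65.6% as deposited, 42.2% with swapped arrays turned and 65.4% after scaling; in high-loss cows it was 60.4%, 49.9% and 62.5%. The cause of these shifts was not tested.

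Of the changes of single probes given in the text, recomputed under alternatives, 373 kept their direction and side of the threshold, 25 lost the call and 10 reversed. The 10 reversals occurred with swapped arrays turned. Over all cows these were 30661.C1_241 (0.42) and 4838.C1_588 (0.14). In low-loss cows they were 4838.C1_588 (0.23) and the next largest positive (-0.023) and negative (0.043) changes, and in high-loss cows 30661.C1_241 (0.21) and the next largest negative change (0.26). For the difference they were the first positive probe (-0.40) and the 2 negative ones (0.027 and 0.15). The within-minus-between correlation of groups was 0.021 with Spearman correlation, -0.021, -0.059, -0.054 and -0.041 with high-loss cow 1, 2, 3 or 4 counted as low-loss, and -0.033 to 0.081 with 1 array left out. Filters on missing values and averaging of probes were not run, since no value was missing and no probe has a gene name. The gene list tests were not run for the same reason.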

Other observations

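The tests of the dye reading, of high-loss cow 5 and of shared probe numbers were chosen after the results were seen, and the counts of other splits were planned. A search for single outlying cows within each group, over 28 sets of values, found 0, where chance alone would give 1.4. The sets were the SD and the share beyond 2-fold of the arrays, and the ratios of the probes described above. Those probes were picked from these data for called changes or the smallest p, which favours a small spread. The search therefore cannot show that no cow was outlying.

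A group of 12 probes moved far, and in opposite directions, in 3 cows whose arrays all have the same dye orientation. Their median log2 ratio was -2.87 in low-loss cow 2, 1.64 in high-loss cow 1 and 2.30 in high-loss cow 3, while the medians on the other 9 arrays lay between -0.32 and 0.49. Changes of these probes beyond 2-fold were not confined to the 3 cows, since only 6 of the 12 probes stayed within 2-fold on all 9 other arrays. Another 11 probes were beyond 2-fold and positive on all 3 arrays. None of the 12 was called over all cows (0 calls). Their identifiers start with a number of 88000 or more in 6 of 12 cases (50.0%), against 6.63% of all tested probes. The group and the bound on the number were both chosen after their values were seen, so no p is attached. Separately, 2 probes were beyond 8-fold on 1 array and within 2-fold on the other 11, the largest at 7.37 in low-loss cow 4.

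The real assignment of dyes gave more calls than the other assignments drawn. Of 100 splits of the 12 arrays into 6 with the once-daily RNA in Cy5 and 6 in Cy3, 1 of 100, the real one, gave as many as 2687 calls over all cows, and the highest other gave 510. The same held for 32 calls in low-loss cows (1 of 100 splits, highest other 1) and 2025 calls in high-loss cows (1 of 100 splits, highest other 1252). Counts this high were thus rare among the splits drawn, at 1 of 100, the smallest share that they could give. A dye effect cannot be excluded, because with the swapped arrays turned the called profile would be the dye term. Nor can an effect of biopsy time, which goes with milking frequency. For the difference between groups, 26 of 100 splits into 5 and 7 cows, the real one included, gave as many as the 1188 probes at an unadjusted p under 0.05, and the highest other gave 4902. Chance is not excluded there. Of the other splits, 3 called at least 1 probe, and the highest called 309, against 0 for the real split.

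The weak correlation between swapped and unswapped arrays may reflect probe-specific dye bias in ratios that the authors had already turned, or ratios of the swapped arrays left as Cy5 over Cy3. The second reading has against it the control spot with the most extreme ratio, at -6.51 or below on swapped arrays (3 of 6 values at the floor) and 6.72 on unswapped arrays. The control spots with small ratios did not change the sign of their mean with orientation. The second reading stays open, also because the control spots were not normalised, dye swaps included. The part of the profile that changes sign with the dye was carried somewhat more evenly by the 12 arrays (coefficient of variation 0.46) than the shared part (0.65), as a dye bias would be, but the bootstrap interval of the difference ran from -0.59 to 0.21. High-loss cow 7 had a loading of 0.023 on the part that changes sign, against a mean of 0.85. The 2 readings cannot be told apart from these values. Orientation also goes with the set of cows and with array order, so a difference of that kind cannot be told apart from either reading.

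In the values as deposited, the number of calls was 2687 with high-loss cow 5 and 4818 without it, which may come from exchanged channels or from RNA of only 1 milking frequency in both channels, as its source names read. Its loading on the profile shared by the other arrays was 0.16, against 0.86 ± 0.50 (SD, n = 11), but low-loss cow 3, with consistent labels, loaded even lower at 0.019. Among probes called without its array, 18 of the 22 beyond 2-fold had the other cows' sign in this cow (median 0.77 in their direction), whereas of all 4818 only 1623 did (median -0.11). Low-loss cow 3 departed likewise in probes called without its own array. There 10 of 19 beyond 2-fold and 1185 of all 3016 (median -0.086) had the other cows' sign. The pattern of high-loss cow 5 was absent with the swapped arrays turned, where the count fell from 7759 to 6315 without it. Its loading was then 1.17 and that of low-loss cow 3 was 1.26 (mean of all 12 arrays 0.85). In high-loss cow 5, 5992 of 6315 probes then had the other cows' sign, but in high-loss cow 7 only 4103 of 9825 (median -0.053). The probes with large changes thus speak against an exchange in the values as deposited. The smaller changes cannot decide, because the ratios of the left-out array still held the dye term. Its median size at the probes called for dye was 0.22, close to that of the changes called over all cows (0.24). Of the swapped arrays, high-loss cow 5 and low-loss cow 3 carried the part that changes sign with the dye most strongly. Like departures occurred in cows with consistent labels. A weak response of high-loss cow 5 was not tested, and the explanations cannot be told apart.

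Probes whose identifiers share their first number may report on related transcripts. For the 433 numbers held by exactly 2 probes, the change over all cows correlated within pairs at r = 0.17 (one-sided permutation p = 2e-04, across probes), so the identifiers carry some information on shared signal. The dye term correlated nearly as much within these pairs, at r = 0.16 (permutation p = 0.00034), so this does not separate a milking effect from a dye effect.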
